A study of Caenorhabditis elegans with 18 samples.

How the data were processed

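Messenger RNA of whole C. elegans was measured by sequencing of rRNA-depleted total RNA. Per the labels' protocols, libraries were made with the NEBNext Ultra II RNA kit and sequenced on an Illumina NextSeq 500, and worms were aliquoted from the harvests used for ribosome profiling, which is not analysed here. The deposited table holds raw read counts per gene for 46934 gene rows, each with a WormBase identifier, and its values are whole numbers with totals that differ between libraries. Per the submitters' processing notes, cutadapt 1.9, Bowtie2 2.3.5.1 and featureCounts of Subread 1.6.2 were used, with no role or order given. The genome build, annotation release, strand setting and treatment of reads that map to several genes are not given in the sources used here. These choices affect gene families with near-identical members (major sperm protein, histone, vitellogenin and some collagen genes) and overlapping or antisense genes, whose counts are uncertain. Bowtie2 is not a spliced aligner, so if genomic sequence was the target, reads across exon junctions would be under-counted in genes with many short exons.

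Columns of the table were assigned only where their names matched the labels. The 3 columns named N2 match the genotype label of the wild-type samples. Their letters A, B and C are not tied to the replicate numbers in the labels, so they served as 3 unnumbered replicates. The other 15 value columns carry strain names that the labels do not pair with an allele, and were not used in any step. Guessing the pairing from column order or from the counts was avoided. As a result the 24 tests fixed before the data were examined (each mutant against the wild type and against the null mutant, overlaps, gene list tests and microRNA site tests) were not run. The annotation used here came without a genome sequence, so 3′ UTR site searches were not made either.

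From the counts, CPM values (the count divided by the library total and multiplied by 1e+06) were computed and summarised as mean ± SD over the 3 libraries. Ratios were taken within each library first. Shares of 30 gene lists, fixed before the data were examined, were the summed counts of their members over the library total. List symbols were matched to names in the table or, failing that, through a table of WormBase identifiers and symbols. Exon lengths (union of annotated exons) and gene positions came from the Ensembl release 115 annotation of WBcel235, joined by identifier. The floor for a count of 0 was 3 counts per library. Reads carry no molecular identifiers, so floors cover counting error only. edgeR 4.0.16 in R 4.3.3 gave TMM and RLE factors and the common dispersion after its filterByExpr filter. No gene-level test was made, since only 1 genotype was available.

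Spread between libraries was the SD of log2(CPM + 0.5) for the 10565 genes with a mean of at least 20 reads, of which 99.99% have an annotated exon length. For each list with at least 5 such members, the median SD was placed among 10000 random lists drawn from the same 20 bins of mean expression. Joint movement was the SD over libraries of the list's median deviation, ranked in the same way. Both were tested on simulated data. With 200 of 10565 genes raised 1.25-fold in 1 of 3 simulated libraries, the changed list lay at percentile 100 and a fold of 1.24 was recovered, and 0 of 20 unchanged lists exceeded the 95th percentile of spread. With a 1.1-fold change 2 of 20 unchanged lists did so, with 1.5-fold 0 and with 2-fold 1. The recovered folds were 1.07 for 1.1, 1.47 for 1.5 and 1.935 for 2, so small changes were underestimated. For joint movement, 1, 0, 2 and 2 of 20 unchanged lists exceeded the 95th percentile with changes of 1.1, 1.25, 1.5 and 2-fold. Genes were simulated independently with 1 dispersion, the unchanged lists were random genes, and the changed list was larger than any real list. These rates therefore do not carry over to real lists, whose genes may vary together. A simulated biological coefficient of variation of 10% was recovered as 9.95%. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.

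The rule for named genes covered alg-1 and the members of the microRNA machinery and heterochronic lists. Its other parts ranked genes by changes between genotypes and did not apply. The most abundant genes, the leading members of the other lists by mean CPM, the genes with the largest spread at a mean of at least 50 CPM, and col-19 were chosen after the data were seen. Alternatives, also chosen after the data were seen, were TMM or RLE library sizes, the protein-coding total as denominator, at least 10 reads for detection, exon length in the alg-1 to alg-2 ratio, other filters for the coefficient of variation, thinning to the lowest total, removal of a length trend, and leaving out each library.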

Results

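The series set out to profile messenger RNA in Caenorhabditis elegans carrying alleles of alg-1, which encodes an Argonaute protein that binds microRNAs. Its labels describe 18 whole-animal libraries in 6 genotypes of 3 libraries each. They comprise the wild type (N2, the standard laboratory strain), an alg-1 null mutant, and 4 alleles, F180del, G199S, V254I and H751L, that carry changes named in human AGO1 in a neurodevelopmental disorder. Worms were synchronised as L1 larvae and harvested after 45 hours of feeding at 20 °C, and ribosomal RNA was depleted before library construction. The count table names its mutant columns by strain, and the labels used here pair no strain name with an allele. The 15 mutant columns were therefore not analysed here, and no comparison between genotypes was made. The results below describe the 3 wild-type libraries, called A, B and C after the letters in their column names.

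The libraries held 6223521 reads assigned to genes in A, 5768308 in B and 5062173 in C. Reads were found for 18277, 17791 and 17819 genes respectively, and at least 10 reads for 12464, 12151 and 12060. A count of 0 allows a level of up to 0.482 CPM (reads of a gene scaled to the library total) in A, 0.52 in B and 0.593 in C, covering counting error only. Protein-coding genes took 94.5% ± 0.6 of the reads (SD, n = 3), ribosomal RNA genes 3.36% ± 0.645 and small nucleolar RNA genes 0.627% ± 0.116. All values below are means ± SD over these 3 libraries unless a single library is named. The labels do not say whether the libraries came from separate cultures, so the spread between them may be technical.

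The gene with the most reads was MTCE.7, a mitochondrial ribosomal RNA, at 20275 ± 4714 CPM. The other mitochondrial ribosomal RNA, MTCE.33, stood at 9394 ± 1820 CPM. Among protein-coding genes the most reads belonged to unc-54, the major body wall muscle myosin heavy chain (14388 ± 363 CPM). The translation elongation factors eef-1A.1 (12694 ± 493 CPM) and eef-2 (8638 ± 304 CPM) and the ribosomal stalk protein gene rla-0 (5850 ± 310 CPM) came next. The mitochondrial ADP/ATP carrier gene ant-1.1 followed at 5485 ± 147 CPM. The non-coding RNA rpr-1 was found at 6087 ± 919 CPM.

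alg-1 (WBGene00000105) was measured with 1382 reads in A, 1236 in B and 1300 in C, a level of 231 ± 22.6 CPM. In the WBcel235 annotation it lies on chromosome X from 13949110 to 13956261 on the forward strand. Its close paralog alg-2 (WBGene00000106, chromosome II from 873212 to 879885) stood at 90.8 ± 2.5 CPM, and alg-5 at 29.5 ± 3.2 CPM. Reads of alg-1 outnumbered those of alg-2 by a ratio of 2.55 ± 0.27, and the ratio was above 1 in 3 of 3 libraries. Per kilobase of annotated exon the ratio was 1.57 ± 0.17. No test of the alg-1 to alg-2 ratio was run, and the smallest p that an exact two-sided sign-flip test allows with 3 libraries is 0.25. How reads shared by the 2 paralogs were counted is not given in the sources used here.

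All 27 measured members of the microRNA machinery list had reads in the wild type, and 17 of them stood at or above 100 CPM. The highest were general RNA-binding and decay factors, namely the poly(A)-binding protein gene pab-1 (3124 ± 35 CPM), vig-1 (1524 ± 52 CPM), tsn-1 (1253 ± 14 CPM) and the DEAD-box helicase gene cgh-1 (787 ± 18 CPM). The CCR4-NOT scaffold gene let-711 was at 705 ± 1 CPM. The GW182 homologs ain-1 and ain-2, which link Argonaute to silencing factors, stood at 101 ± 4.9 and 110 ± 9.7 CPM. The ratio of ain-1 to ain-2 was 0.92 ± 0.109 by read count and 1.12 ± 0.133 per kilobase of exon. It was above 1 in 1 of 3 libraries by read count and in 2 per kilobase, and no test of it was run. The processing enzymes were lower, with dcr-1 (Dicer) at 86.4 ± 6.6 CPM, drsh-1 (Drosha) at 16.8 ± 2.2 CPM and its partner pash-1 at 15.7 ± 1.3 CPM. The list as a whole took 1.06% ± 0.01 of the reads, and pab-1, vig-1 and tsn-1 gave 55.9% of the list's reads. Its share is therefore not comparable with that of a list of Argonautes alone. Argonautes of the siRNA and piRNA pathways took 0.214% ± 0.006, led by csr-1 (334 ± 10.6 CPM), hrde-1 (308 ± 11.3 CPM) and wago-1 (294 ± 16 CPM).

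Of the 29 genes in the heterochronic list, which holds regulators of developmental timing, 9 stood at or above 100 CPM, 11 between 10 and 100 CPM and 9 below 10 CPM. The period homolog lin-42 was the highest at 463 ± 52 CPM. lin-41, a let-7 target in textbook accounts, was at 93.3 ± 1.9 CPM, the lin-4 target lin-14 at 56.3 ± 4 CPM, and the larval-to-adult transcription factor gene lin-29 at 36.8 ± 5.3 CPM. The lower members included hbl-1 (17.8 ± 1.2 CPM) and lin-28 (10.8 ± 0.8 CPM). Reads of lin-29 exceeded those of lin-28 by a ratio of 3.41 ± 0.371, in 3 of 3 libraries, or 2.15 ± 0.234 per kilobase of exon. The ratio of lin-29 to lin-14 was 0.653 ± 0.047 by read count and 1.04 ± 0.07 per kilobase of exon. Among the microRNA genes of the list, let-7 had 24, 19 and 21 reads over an annotated gene of 1732 exonic bases, lin-4 and mir-84 had 0 reads in every library, mir-48 had 1 read in B alone, and mir-241 had 4, 8 and 2 reads. Levels of mature microRNAs were not analysed here.

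**Figure D1:**
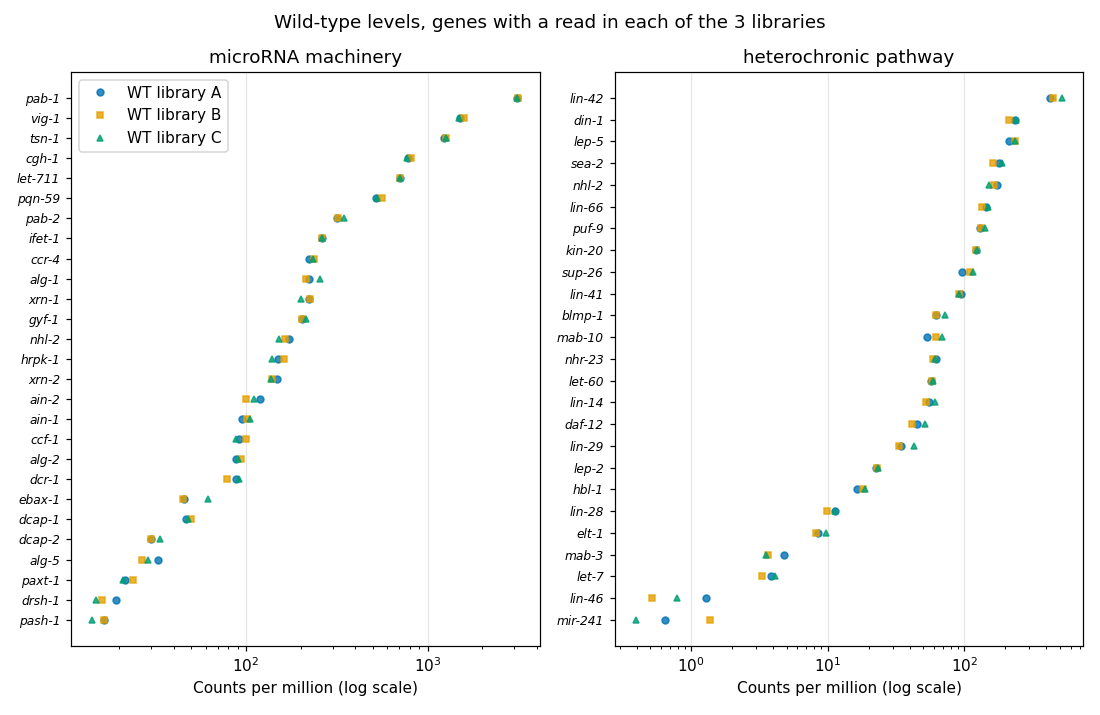
CPM (horizontal log axis) of the microRNA machinery and heterochronic genes that had a read in each of the 3 wild-type libraries, with 1 symbol per library. pab-1 lies near 3124 CPM and alg-1 near 231 CPM, and the symbols of most genes above 100 CPM nearly overlap.

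Read shares of the other lists depend on which genes each list holds and do not measure the share of a tissue in the sample. Ribosomal protein genes took 11.6% ± 0.5 of the reads, cuticle collagens 5.27% ± 0.26 and body wall muscle genes 4.95% ± 0.16. The leading collagens were dpy-4 (3042 ± 92 CPM), dpy-13 (2756 ± 130 CPM) and col-73 (2229 ± 94 CPM), and beside unc-54 the leading muscle genes were act-4 (5291 ± 337 CPM) and the paramyosin gene unc-15 (4396 ± 125 CPM). Intestinal genes took 1.39% ± 0.09, led by the aspartyl protease gene asp-1 (4458 ± 357 CPM), and summed reads of the muscle list exceeded those of the intestine list by a ratio of 3.57 ± 0.17. Synaptic and neuronal genes took 0.156% ± 0.006, with egl-3 (169 ± 5 CPM) and egl-21 (135 ± 2.9 CPM), both neuropeptide-processing enzymes, among the highest. Neuropeptide genes took 0.146% ± 0.001, of which nlp-77 (622 ± 15 CPM) was the highest. Pharyngeal genes took 0.118% ± 0.015. The vulva and somatic gonad list took 1.51% ± 0.04, nearly all of it from unc-54, which is chiefly a body wall muscle gene, and without unc-54 the share was 0.07%.

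Genes of the germline were readily measured. The oocyte and eggshell list took 0.36% ± 0.024 of the reads, led by cbd-1 (667 ± 46 CPM) and gld-1 (410 ± 24 CPM), and the spermatogenesis list 0.23% ± 0.018, led by ssq-2 (108 ± 8.2 CPM) and msp-64 (103 ± 11.8 CPM), whose near-identical relatives can share reads. Summed spermatogenesis reads were 0.639 ± 0.02 of the oocyte reads, below 1 in 3 of 3 libraries. General germline and meiosis genes took 0.208% ± 0.01, with glh-1 at 430 ± 19.5 CPM and pgl-1 at 322 ± 14.6 CPM. Cell cycle and replication genes took 0.236% ± 0.008 and histone genes 0.263% ± 0.02. The 6 vitellogenin genes, which encode yolk proteins made in the intestine, took 0.692% ± 0.116, with vit-6 at 3364 ± 512 CPM and vit-2 at 2353 ± 314 CPM. The adult-expressed collagen gene col-19 was at 307 ± 75.7 CPM. The early embryonic list took 0.0198% ± 0.0005, of which skn-1 alone gave 169 ± 5.4 CPM, and 6 of its 18 members had no read in any library.

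Genes of the cuticle and the molt made up further shares. Molting and apical matrix genes took 0.552% ± 0.055, led by the protease inhibitor gene mlt-11 (1080 ± 176 CPM) and by noah-1 (506 ± 54 CPM), and hedgehog-related genes 0.56% ± 0.014, led by grl-16 (1378 ± 17 CPM). Nuclear genes of mitochondrial respiration took 1.7% ± 0.05 and the 12 mRNAs of the mitochondrial genome 0.683% ± 0.086. Metabolic and stress lists were represented by lipid metabolism genes (0.885% ± 0.028), innate immune effectors (0.928% ± 0.098), heat shock and unfolded protein genes (0.753% ± 0.026), proteasome genes (0.513% ± 0.018), insulin pathway targets (0.346% ± 0.01) and detoxification genes (0.251% ± 0.007). Leading members were acdh-1 (1683 ± 48 CPM), irg-7 (2393 ± 450 CPM), hsp-1 (3159 ± 166 CPM), rpn-1 (441 ± 21 CPM), icl-1 (1455 ± 71 CPM) and gst-1 (140 ± 8 CPM). The cytoplasmic ribosomal RNA list took 0.391% ± 0.037. The list of small nuclear, nucleolar and spliced leader RNA names matched 39 reads in all, and 29 of its 43 members had none. This reflects the names that the list holds, since all genes classed as small nuclear RNA took 0.0315% ± 0.0058 of the reads.

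**Figure D2:**
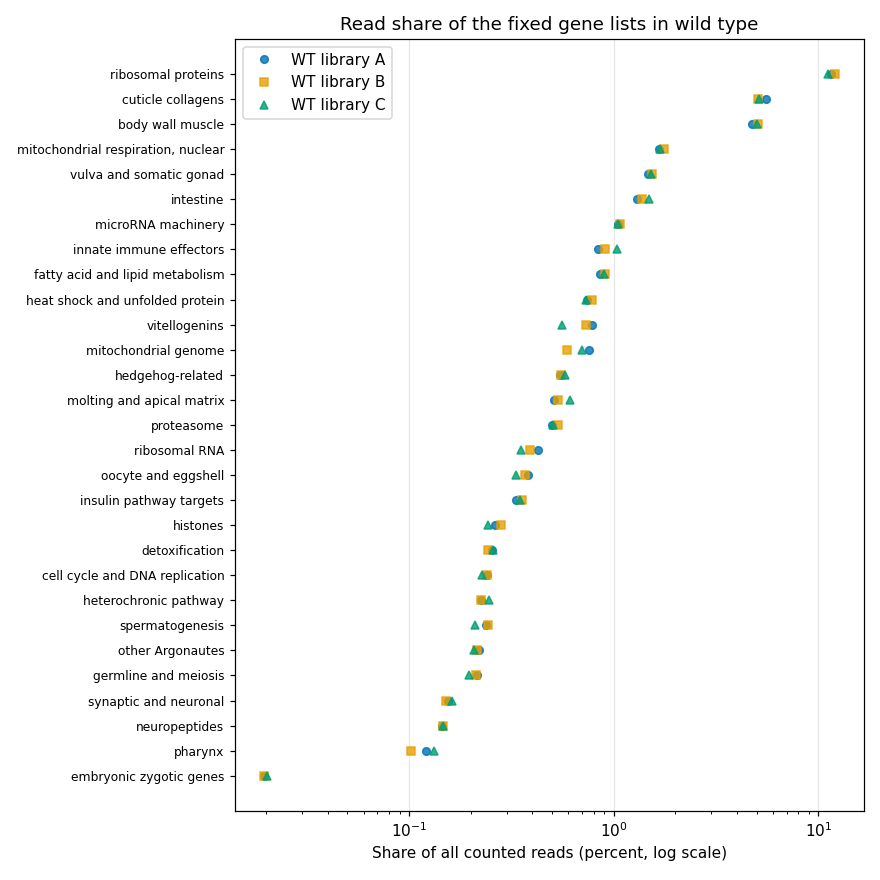
Share of all counted reads (percent, horizontal log axis) taken by each fixed gene list in the 3 wild-type libraries, with 1 symbol per library. Ribosomal proteins (11.6%) take the largest share, and the vitellogenins show library C (0.56%) apart from A (0.781%) and B (0.734%).

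The 3 libraries were alike for most genes. The common biological coefficient of variation, edgeR's estimate of the spread beyond counting noise, was 6.71% over 11602 genes. It was 5.37% without library C, 6.89% without A and 7.79% without B. Among 2906 protein-coding genes with a mean of at least 50 CPM, the median coefficient of variation was 5.25%, and 35 genes exceeded 20%. Between 2 libraries, 3.74% of genes in A and B, 5.12% in A and C and 4.75% in B and C differed by more than 1.5-fold. Chi-square per degree of freedom between these pairs was 3.56, 3.98 and 4.54, so none of the 3 was a second copy of another.

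The spread was not even over gene groups. The largest relative spreads among well-measured protein-coding genes belonged to yolk and collagen genes. vit-5 was at 573 CPM in A, 438 in B and 270.2 in C, and col-119 was at 176, 107 and 83.2 CPM. col-80, vit-1 and col-178 followed, each with its highest level in A and its lowest in C. Of 27 lists with at least 5 measured members, 8 had a median SD of log2(CPM + 0.5) above the 95th percentile of 10000 random lists matched on mean level. These were vitellogenins (median SD 0.34), mitochondrial genome mRNAs (0.24), innate immune effectors (0.17), molting and apical matrix genes (0.17), cuticle collagens (0.16), histones (0.16), hedgehog-related genes (0.15) and oocyte and eggshell genes (0.13). The microRNA machinery list had a median SD of 0.07, at percentile 33.3 of its matched lists, and the heterochronic list 0.10, at percentile 67.3. Without library C only 2 of the 27 lists, cuticle collagens and mitochondrial genome mRNAs, exceeded the 95th percentile. Without library A, innate immune effectors lay at percentile 87.4 and hedgehog-related genes at 70.3. Histones lay at 83.1 once a trend on exon length was removed, which can take out part of the movement of genes alike in length. These percentiles describe the 3 libraries and are not tests across samples.

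**Figure D3:**
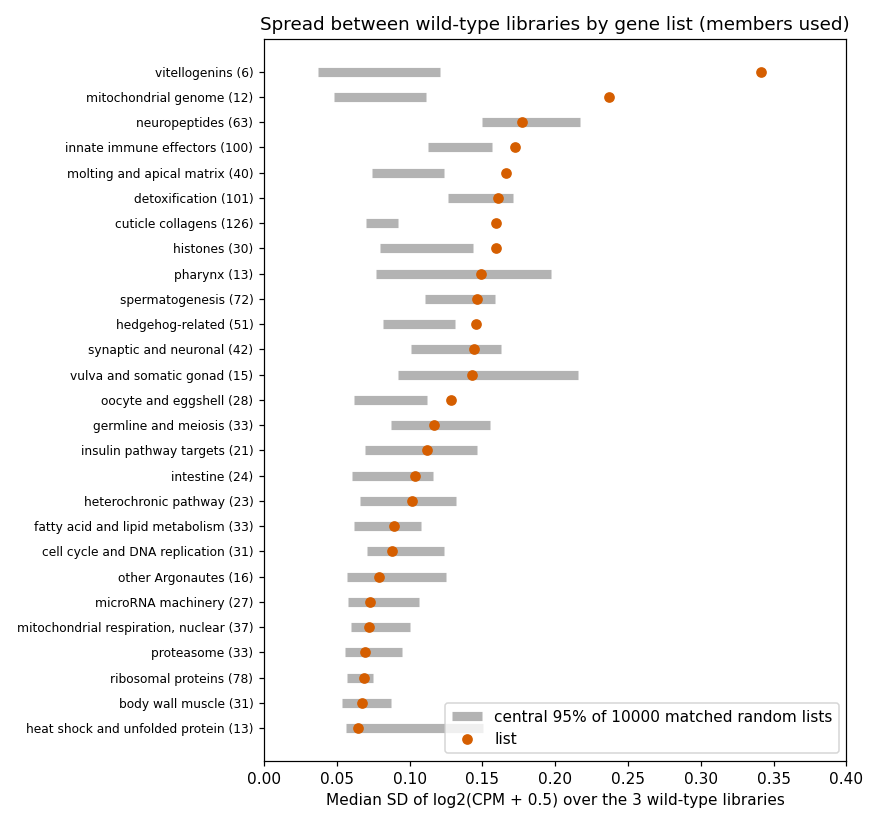
Median SD of log2(CPM + 0.5) over the 3 wild-type libraries for each gene list (points, with the number of members used in brackets) and the central 95% of 10000 random lists matched on mean level (grey bars). The vitellogenins lie at 0.34 and the mitochondrial genome mRNAs at 0.24, to the right of their grey bars.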

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

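The alternatives fixed before the data were examined were not run, because each belongs to a comparison between genotypes. The alternatives below were chosen after the data were seen. No paired analysis was possible because the mutant columns were not matched to genotypes and the wild-type columns carry no replicate number. The alg-1 level of 231 CPM stayed at 231 under TMM and RLE library sizes and was 245 under the protein-coding total. It was 236 without A, 239 without B and 218 without C. Leaving out 1 of 3 libraries cannot move a mean by as much as its SD, so this is no test of stability. The SD itself was 22.6 CPM with all 3 libraries and 5.5 without C. The alg-1 to alg-2 ratio of 2.55 was 1.57 once exon length was taken into account, since alg-1 has more annotated exon (6696 bases against 4142). These lengths are unions of all annotated exons and may exceed the length of the transcripts expressed. The mean number of genes detected per library was 17962 with at least 1 read and 12225 with at least 10 reads. The biological coefficient of variation of 6.71% ranged from 5.37% without replicate C to 7.79% without replicate B, and stayed within 6.39% to 6.86% under the other filters and factors. The protein-coding total as denominator raised list shares, for example cuticle collagens from 5.27% to 5.58%. The number of lists with a spread above the 95th percentile was 8, and ran from 7 to 10 under the other scalings, thinning and length correction. It was 9 without A, 10 without B and 2 without C. Of the 8, only cuticle collagens and mitochondrial genome mRNAs exceeded the 95th percentile without C. Without A, innate immune effectors lay at percentile 87.4 and hedgehog-related genes at 70.3. Histones lay at percentile 83.1 once the length trend was removed. That trend was the median deviation of genes of like exon length, list members included. For a list of genes alike in length, its removal can take out part of the list's own movement. The number of lists with a joint movement above the 95th percentile was 20, and was 18 under TMM, 20 under the protein-coding total, 21 after thinning, 17 with the length trend removed, 16 without A, 19 without B and 11 without C. For genes below about 10 CPM, the microRNA genes among them, counting noise is a large part of the spread. Why the microRNA genes had few reads was not tested.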

Other observations

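The predictions for cuticle collagens, molting genes and hedgehog-related genes were written before the spread was computed; the other tests here were chosen after the result was seen. No difference of genotype bears on these patterns, since all 3 libraries are wild type. Several gene groups deviated together in the wild-type libraries. Intestinal genes had a median deviation from their mean over the libraries of -0.10 (log2) in A, -0.01 in B and 0.10 in C, and innate immune effectors -0.07, -0.01 and 0.07. Germline and meiosis genes stood at 0.06, 0.03 and -0.09, and spermatogenesis genes at 0.06, 0.08 and -0.12. Without library C the joint movement lay at percentile 98.5 for intestinal genes, 92.1 for innate immune effectors, 71.9 for germline and meiosis genes and 27.5 for spermatogenesis genes. Ribosomal protein genes stood at 0.00, 0.06 and -0.07, but their joint movement lay at percentile 91.4 once the length trend was removed and 85.3 without C. The random lists do not keep any shared regulation of genes, so members that vary together can give high percentiles by that alone. In all, 20 of the 27 lists had a joint movement above the 95th percentile of matched random lists. Of these 20, 18 exceeded it under TMM, 16 with the length trend removed, 15 without A, 17 without B and 11 without C. The heterochronic list was among those that did not, at percentile 88.0 under TMM, 94.7 with the length trend removed and 90.6 without C.

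Genes of the molting cycle spread more between wild-type libraries than genes of like level. Cuticle collagens lay at percentile 100 of 10000 matched lists, molting and apical matrix genes at percentile 100 and hedgehog-related genes at percentile 99.8. Differences in the point of the molting cycle at harvest are a candidate explanation. Median deviations in A, B and C were 0.08, -0.04 and -0.01 for collagens, -0.07, -0.03 and 0.12 for molting genes and -0.02, -0.04 and 0.09 for hedgehog-related genes. The last 2 lists were thus highest in C and the collagens in A. The collagen genes of largest spread, col-119, col-80 and col-178, were highest in A and lowest in C, as the vitellogenins were. So was the adult-expressed col-19 (0.37, -0.03 and -0.34). The spread of the collagens therefore does not tell the point of the molting cycle from developmental age. The spread of the collagens held percentile 100 without any 1 library, though their joint movement lay at percentile 39.6 without A, while without C the spread of the molting list lay at percentile 79.0 and the hedgehog-related list at 51.6, and without A the hedgehog-related list lay at 70.3. Other conditions that alter cuticle genes between cultures stay open and were not tested.

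The vitellogenins had a median deviation of 0.25 (log2) in A, 0.11 in B and -0.39 in C, a joint movement of 0.33 at percentile 100. After the length trend was removed it was 0.36, still at percentile 100, which argues against recovery that depends on transcript length. Thinning every library to the lowest total left the vitellogenins at 0.33 and percentile 100. It moved some lists of weaker joint movement (neuropeptides from percentile 80.1 to 54.7 and the microRNA machinery from 24.5 to 51.8). CPM is already scaled to the library total, and each vitellogenin gene had at least 481 reads per library. Thinning could therefore hardly lower their joint movement, and it does not decide on depth as a cause. The oocyte and eggshell list had the same order, at 0.09, 0.04 and -0.12, with a joint movement at percentile 100, an order that had been seen in its read share before this test. Cultures that differed slightly in developmental age at harvest would give such an order, but the pattern rests largely on library C. Without C the joint movement lay at percentile 97.3 for the vitellogenins and 77.9 for the oocyte list, and their spread at 87.8 and 4.39. A low level in C was not particular to oocyte genes. Germline and meiosis genes (0.06, 0.03 and -0.09) and spermatogenesis genes (0.06, 0.08 and -0.12) were lowest there as well. Library C also had the lowest share of small nucleolar RNA reads (0.695%, 0.693% and 0.492% in A, B and C). The non-coding RNA rpr-1 was lowest there too, with deviations of 0.17, 0.09 and -0.26. The intestine list, in whose tissue yolk is made, moved the other way at -0.10, -0.01 and 0.10. A technical difference of library C was not tested and cannot be told apart from age here. Reads shared among near-identical vitellogenin genes stay open as a reason why vit-3, vit-4 and vit-5 move alike, while vit-2 and vit-6 also had their lowest level in C.

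The mitochondrial ribosomal RNAs and the list of mitochondrially encoded mRNAs were lowest in library B. MTCE.7 was 1.48 times and MTCE.33 1.46 times as high in A as in B, and the mRNAs ctc-1 and ctb-1 were 1.24 and 1.28 times as high. The differing ribosomal RNA shares that uneven depletion would leave shift every other gene by at most 0.017 (log2) between these libraries. The mRNAs had a range of 0.40, which that shift is too small to give. The shift is common to all genes and could not set a single list apart, so it does not decide on depletion as a cause. Direct loss of mitochondrial mRNA during depletion was not tested. For the ribosomal RNAs uneven depletion stays open, since their range of 0.58 exceeded that of the mRNAs by 0.18, which decides neither way. An earlier form of the test asked for 1 order over the libraries in both kinds of RNA and left the question undecided, because MTCE.33 shared the order of the mRNAs and the mean of the 2 ribosomal RNAs did not; the tests given here were set up after that. The cytoplasmic ribosomal RNA rrn-3.1 had its lowest level in C instead, with deviations of 0.11, 0.00 and -0.11.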
